A study of Mus musculus with 13 samples.

How the data were processed

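Genomic DNA from the cortex of male mice was sonicated, and its 5hmC was glucosylated with an azide-bearing sugar, coupled to biotin and pulled down on streptavidin beads before sequencing libraries were made, per the labels' protocols. The 12 capture libraries fall into WT (4), 5xFAD (2), Tet1(+/-) (2) and FAD/Tet1(+/-) (4), and 1 further library is an input, labelled WT3. Reads were trimmed with Trimmomatic 0.36 and handled with SAMtools 1.9, peaks were called with MACS2 and positions refer to mm9, per the submitters' processing notes, where the role of each tool is inferred from its usual use. The aligner, the MACS2 version and settings, and whether every library of a genotype was pooled are not given in the sources used here. The peak names in the deposited lists name 1 genotype and the WT3 input each, so every list was treated as a single call per genotype. The input is labelled as WT, and no input of another genotype is named.

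Each deposited list gives, per peak, the position, a score, a fold enrichment ratio, a −log10 p, a −log10 q and the summit. The score deposited by the authors equals 10 times the −log10 q, cut to a whole number. The fold enrichment is the authors' ratio of capture to the local input background at the summit. The smallest −log10 q in the authors' deposited tables corresponds to a q of 0.05. These per-peak values were used to describe, rank and filter peaks within a list, to count peaks past a threshold in each list, and to recover depth as described below.

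Peaks on the autosomes, X and Y were analysed, and the 5, 6, 1 and 5 mitochondrial peaks of WT, 5xFAD, Tet1(+/-) and FAD/Tet1(+/-) were kept apart. Peaks of separate lists were called shared at an overlap of at least 1 bp. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. The chance level is the mean over 1000 draws (seed 11) in which a list was shifted circularly within the span of each chromosome. That level leaves out similarity that the shared input library gives all lists. Lists of equal length hold the 13256 peaks with the highest −log10 p of each list, the length of the shortest. The weakest peak kept had a −log10 p of 7.69 in WT, 3.76 in 5xFAD, 14.3 in Tet1(+/-) and 6.41 in FAD/Tet1(+/-). Equal lists therefore differ in stringency. Peaks gained or lost between WT and 5xFAD were compared with shared peaks matched on fold enrichment in 10 bins. Peak density is peaks per Mb between the outermost peaks of a chromosome over all lists. Merged regions join overlapping peaks of the 4 lists.

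Read totals were not used here, so relative depth was recovered from the deposited values. MACS2's fold enrichment is a ratio of pileup to background with 1 added to both, and its p-value is a Poisson tail. When the capture is scaled to the input depth, pileups are whole multiples of what 1 fragment is worth. The spacing of the fold values therefore gives the capture depth over input, and fold and p together give the fragments and background at each summit. This solved every peak of 3 lists and all but 7 of Tet1(+/-), where p was too small to be represented. The median mismatch in log10 p was at most 0.000114, against at least 2.15 for the next-best solution. On simulated lists made with the real numbers of peaks, the depth ratio was recovered with an error of at most 2.7e-05 and at least 92.6% of fragment counts were recovered. Because larger captures were scaled down to the input, p-values in all lists refer to about the same nominal depth, although deeper captures carry less counting noise.

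The comparisons, the matching, the equal lists and the alternatives were fixed before the data were examined, except where stated. The alternatives were a −log10 q or a fold enrichment of at least 5, autosomes only, merging peaks within 500 bp, an overlap of 50% of the peak, a distance of up to 1 kb, ranking by fold enrichment, shorter equal lists of 6628 peaks and peaks at the list-wide background only. The last was chosen after seeing the data. The rule for regions named in the text was the 3 peaks with the highest fold enrichment in each direction of each comparison among peaks that the other full list does not overlap. The rule would have named genes had an annotation of mm9 been used. The gene table used here is of another build, GRCm38.p6, so no peak was assigned to a gene, and the 12 gene lists fixed beforehand, the shares by genomic feature, and Tet1 and Thy1 were not scored. The chromosome 9 place, the windows of 1 Mb and the recovered depths were examined after seeing the data.

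Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. No values per library were used here, so no test between genotypes was made.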

Results

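5-Hydroxymethylcytosine (5hmC), the oxidation product of 5-methylcytosine made by TET enzymes, was mapped by chemical capture in the cortex of male mice of 4 genotypes. 5xFAD mice carry mutant human amyloid precursor protein and presenilin transgenes and are a model of amyloid deposition. Tet1(+/-) mice carry a single functional copy of Tet1, which encodes a TET enzyme, and FAD/Tet1(+/-) mice combine both. The labels name 4 WT, 2 5xFAD, 2 Tet1(+/-) and 4 FAD/Tet1(+/-) capture libraries and 1 input library, labelled WT3. The measurements are 4 peak lists, 1 per genotype, each called against the WT3 input. There are therefore no replicate values, and differences between genotypes carry no p-value. The intervals given are exact (Clopper-Pearson) 95% intervals and cover counting error only. All positions are in mm9, and fold enrichments are the authors' values for single peaks over input.

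The number of regions called as 5hmC-enriched differed widely between genotypes. The Tet1(+/-) list was the longest, with 79360 peaks covering 34.4 Mb. The WT list held 22358 peaks over 9.03 Mb, the FAD/Tet1(+/-) list 18043 peaks over 6.48 Mb and the 5xFAD list 13256 peaks over 4.98 Mb. The order of the 4 genotypes was the same among strongly enriched regions. Peaks with a fold enrichment of at least 10 numbered 3014 in Tet1(+/-), 932 in WT, 506 in FAD/Tet1(+/-) and 99 in 5xFAD. Median peak widths lay close together, at 347 bp in Tet1(+/-), 338 bp in WT, 321 bp in 5xFAD and 307 bp in FAD/Tet1(+/-). Within lists, the median fold enrichment was 4.59 in WT (interquartile range 3.88 to 5.60), 3.94 in 5xFAD (3.45 to 4.61), 4.47 in Tet1(+/-) (3.73 to 5.69) and 4.42 in FAD/Tet1(+/-) (3.73 to 5.39).

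The depth behind each list was recovered from the fold enrichments and p-values of its peaks. Capture libraries behind the WT list held 2.49 fragments per input fragment, those behind FAD/Tet1(+/-) 2.47, those behind 5xFAD 1.54 and those behind Tet1(+/-) 1.01. The longest list thus came from the lowest depth. The median number of capture fragments at a summit was 47 in WT, 27 in 5xFAD, 18 in Tet1(+/-) and 47 in FAD/Tet1(+/-). The numbers of called regions reflect these libraries, and no second list per genotype was used here to separate genotype from library preparation.

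**Figure D1:**
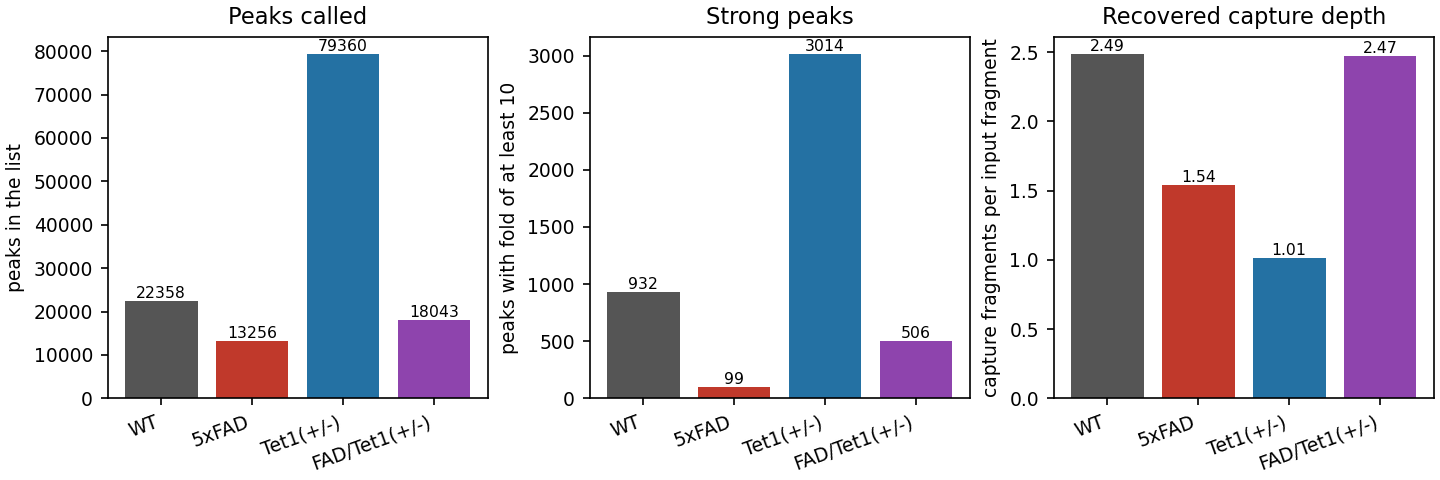
Bars give, for each genotype's list, the number of peaks on the autosomes, X and Y (left), the number of peaks with a fold enrichment of at least 10 (middle) and the recovered capture depth in fragments per input fragment (right). Tet1(+/-) has the most peaks (79360) and the lowest depth (1.01), and 5xFAD has the fewest peaks (13256).

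The comparison of 5xFAD with WT addressed which 5hmC regions accompany the amyloid transgenes. In lists of equal length, regions called in these genotypes overlapped less than those of any other pair of the 4 lists. Of the 13256 peaks of 5xFAD, 3877 overlapped a WT peak (29.2%, 28.47 to 30.03), and of the 22358 WT peaks, 3850 overlapped a 5xFAD peak (17.2%, 16.7 to 17.7). Randomly shifted lists gave 0.693% and 0.411%. With peaks at the list-wide background only, the shares were 24.8% and 10.2%. With each list held to its 13256 strongest peaks by p, 21.0% (20.3 to 21.7) of 5xFAD peaks overlapped WT. These equal lists reached down to a −log10 p of 3.76 in 5xFAD and 7.69 in WT, which can lower their overlap. Among peaks with a fold enrichment of at least 5, these shares of 5xFAD peaks were 49.2% in full and 33.2% in equal lists. Many strong WT regions were not called in 5xFAD either. The 3 strongest WT peaks were called in both, with folds of 34.7, 32.5 and 29.9 in WT and 23.2, 15.8 and 14.0 in 5xFAD. The 3 strongest 5xFAD peaks also had lower folds in 5xFAD than in WT. A region without a call may still carry signal under the threshold, and signal outside called peaks was not used here. Among the 2236 WT peaks in the strongest 10% by fold enrichment, 39.3% (37.3 to 41.4) overlapped a 5xFAD peak, 94.1% (92.990 to 94.996) a FAD/Tet1(+/-) peak and 99.2% (98.7 to 99.5) a Tet1(+/-) peak. In the other direction, 75.2% (72.8 to 77.5) of the 1326 strongest 5xFAD peaks overlapped WT.

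The strongest WT regions absent from 5xFAD were single narrow peaks on 3 autosomes. They lay at chromosome 10, 128632347 to 128632747 (fold enrichment 19.3), chromosome 5, 43141033 to 43141431 (17.9), and chromosome 1, 22272071 to 22272494 (17.8). Each was also called in Tet1(+/-) and in FAD/Tet1(+/-). The strongest 5xFAD regions absent from WT were neighbours on chromosome 9, at 43849890 to 43851082 (13.6) and 43852341 to 43853618 (12.5). Both were also called in FAD/Tet1(+/-) and in neither list without the transgenes. With a single input, labelled WT3, extra copies of the place in carriers could not be told apart from more 5hmC per copy. The recovered input level was itself raised there, at 10 and 15 fragments at the 2 peaks against a list-wide background of 3.04. The reason was left open. The next, at chromosome 9, 47500101 to 47501393 (8.42), was called in Tet1(+/-) and FAD/Tet1(+/-) too.

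**Figure D2:**
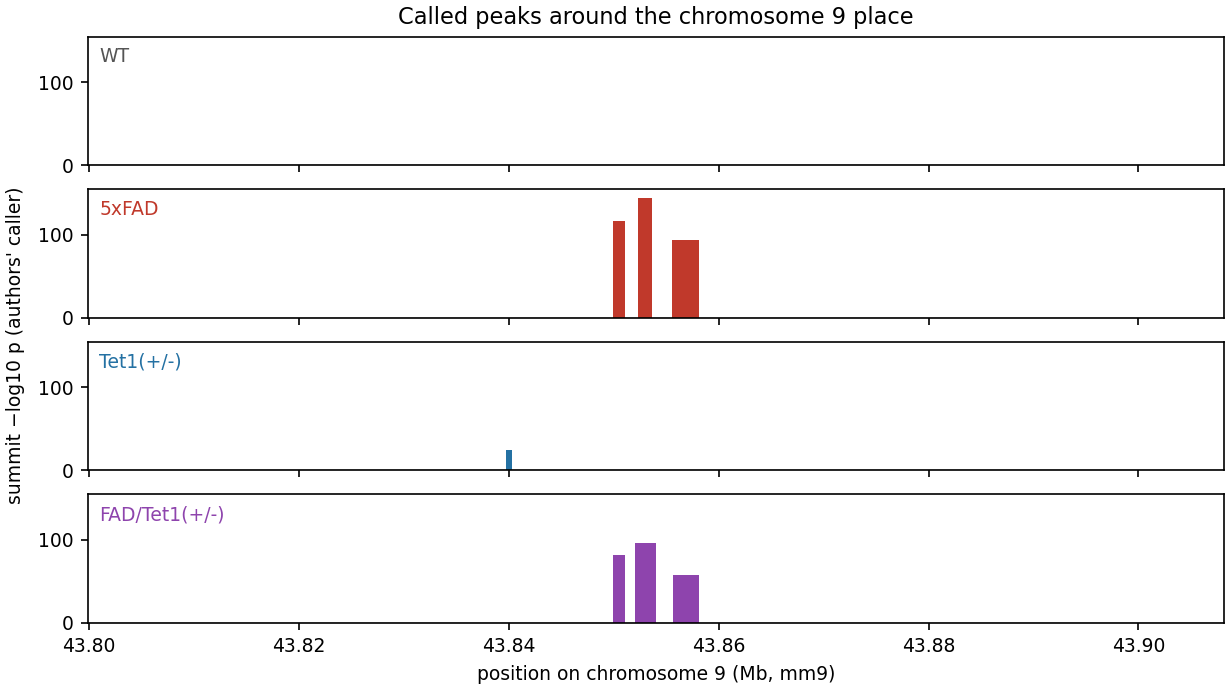
Bars give each called peak within 50 kb of the chromosome 9 place, with its extent in mm9 as the width and the authors' −log10 p at the summit as the height, in 1 panel per genotype. Peaks stand at the place in 5xFAD and FAD/Tet1(+/-), and none in WT or Tet1(+/-), whose 1 nearby peak starts at 43839691.

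**Figure D3:**
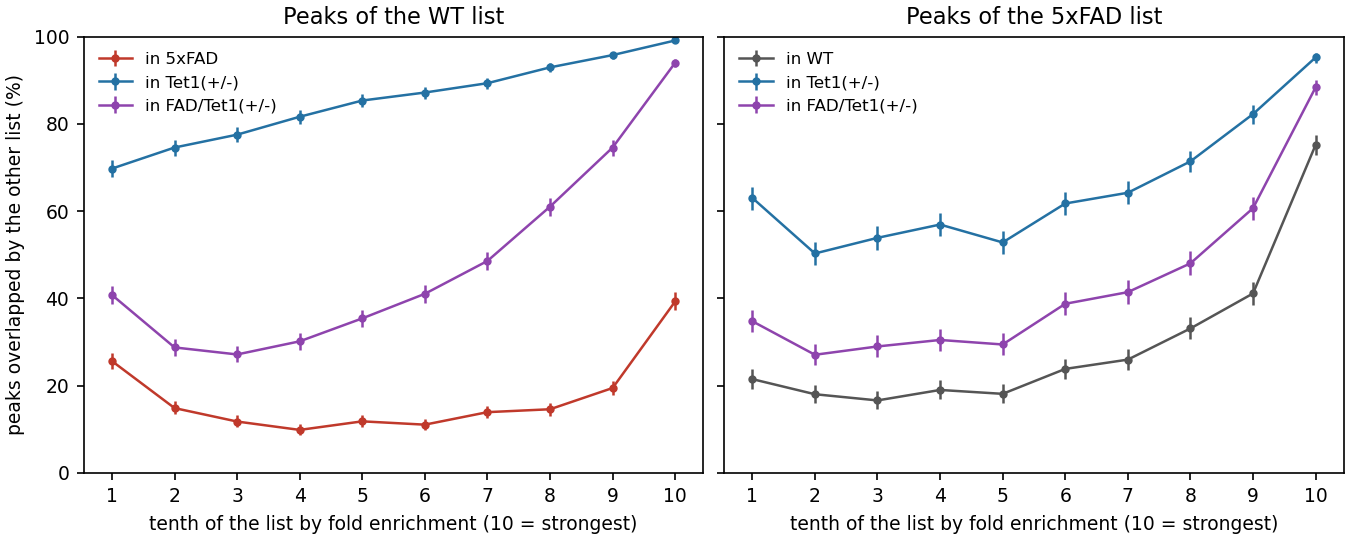
Points give the percentage of WT peaks (left) and 5xFAD peaks (right) overlapped by each other list, by bins of 10% of the list in order of fold enrichment, with exact 95% binomial intervals as bars. In the strongest 10% of WT peaks, 39.3% were overlapped by 5xFAD, against 94.1% by FAD/Tet1(+/-) and 99.2% by Tet1(+/-).

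The comparison of Tet1(+/-) with WT addressed the effect of losing a Tet1 copy without the amyloid transgenes. With full lists, most WT regions were also called in Tet1(+/-), whose list held many more. Of WT peaks, 19081 overlapped a Tet1(+/-) peak (85.3%, 84.9 to 85.8), against 2.59% after random shifts. Of Tet1(+/-) peaks, 18879 overlapped WT (23.8%, 23.5 to 24.1), and 60481 did not. In lists of equal length, 50.5% (49.6 to 51.3) of WT peaks overlapped Tet1(+/-), and 49.5% (48.6 to 50.4) of Tet1(+/-) peaks overlapped WT. The strongest Tet1(+/-) regions absent from WT lay at chromosome 17, 18329626 to 18329965 (fold enrichment 29.7), chromosome 13, 77578072 to 77578324 (26.1), and chromosome 13, 7127752 to 7128353 (26.0). The first and the third of these were called in both 5xFAD and FAD/Tet1(+/-), and the second in no other list. WT regions absent from Tet1(+/-) were weaker within their list. The strongest were at chromosome X, 120726792 to 120727461 (10.8), chromosome X, 28219221 to 28219552 (9.33), and chromosome 3, 106696736 to 106697061 (9.20).

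The comparison of FAD/Tet1(+/-) with 5xFAD addressed how partial loss of Tet1 alters the 5hmC profile of the amyloid model. FAD/Tet1(+/-) held more regions than 5xFAD and shared fewer of them with 5xFAD than with WT. WT and FAD/Tet1(+/-) were also alike in depth, at 2.49 and 2.47 fragments per input fragment, against 1.54 in 5xFAD. The labels name 4 libraries for each of those 2 genotypes and 2 for 5xFAD. Likeness in depth could therefore not be told apart from likeness by genotype. Of its 18043 peaks, 5672 overlapped 5xFAD (31.4%, 30.8 to 32.1), 10870 overlapped WT (60.2%, 59.5 to 61.0) and 15499 overlapped Tet1(+/-) (85.9%, 85.4 to 86.4). In lists of equal length the shares were 34.4% (33.6 to 35.2) with 5xFAD, 56.8% (55.9 to 57.6) with WT and 52.8% (51.9 to 53.6) with Tet1(+/-). Of 5xFAD peaks, 42.8% (42.0 to 43.7) overlapped FAD/Tet1(+/-).

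The strongest FAD/Tet1(+/-) regions absent from 5xFAD were called in WT and in Tet1(+/-). They lay at chromosome 10, 128632345 to 128632704 (fold enrichment 14.3), chromosome X, 87954854 to 87955150 (14.3), and chromosome 5, 43141080 to 43141416 (14.1). The first and the third were also among the 3 strongest WT regions absent from 5xFAD. In the other direction the strongest were at chromosome 11, 41746930 to 41747243 (8.10), chromosome 10, 128260962 to 128261301 (7.94), and chromosome 12, 56515974 to 56516334 (7.46). The strongest FAD/Tet1(+/-) regions absent from Tet1(+/-) were the chromosome 9 neighbours, at 43849888 to 43851110 (10.8) and 43852052 to 43853986 (9.25). Chromosome 8, 19883995 to 19884392 (8.41), followed. The neighbours were also called in 5xFAD, and the chromosome 8 region in WT and 5xFAD. The strongest Tet1(+/-) regions absent from FAD/Tet1(+/-) were at chromosome 13, 77578072 to 77578324 (26.1), chromosome 10, 129656426 to 129657308 (26.0), and chromosome 18, 5753639 to 5754142 (25.5). Of these, the chromosome 10 region was also called in WT, and the others in no other list.

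WT regions missing from 5xFAD were found in FAD/Tet1(+/-) more often than 5xFAD regions missing from WT. Of 18508 WT peaks absent from 5xFAD, 7405 overlapped FAD/Tet1(+/-) (40.0%, 39.3 to 40.7). Of 9379 5xFAD peaks absent from WT, 2292 did (24.4%, 23.6 to 25.3). Peaks shared by WT and 5xFAD, matched on fold enrichment, overlapped FAD/Tet1(+/-) in 84.4% and 82.3%. They were chosen for being called in both lists, which by itself favours a call in a further list. Their shares in Tet1(+/-) were 94.3% and 93.5%. In lists of equal length, FAD/Tet1(+/-) overlapped 47.8% (46.8 to 48.7) of 10500 WT peaks absent from 5xFAD. It overlapped 20.1% (19.4 to 20.9) of 10468 5xFAD peaks absent from WT. With peaks at the list-wide background only, the latter share was 11.8%. Tet1(+/-) without the transgenes held 83.3% (82.7 to 83.8) of the WT peaks absent from 5xFAD and 52.7% (51.7 to 53.8) of the 5xFAD peaks absent from WT. In equal lists, these shares were 43.2% (42.3 to 44.2) and 14.3% (13.6 to 15.0). The WT and FAD/Tet1(+/-) lists were alike in depth, at 2.49 and 2.47 fragments per input fragment, against 1.54 in 5xFAD. The WT and 5xFAD classes were not matched to each other on fold enrichment, and the list medians were 4.59 and 3.94. A difference in detection could therefore not be told apart from one of genotype.

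Merging the 4 lists of equal length gave 31461 regions, of which 2031 were held by all 4 genotypes. Among regions held by 3 genotypes, 3120 were missing from 5xFAD alone, 805 from WT alone, 411 from Tet1(+/-) alone and 118 from FAD/Tet1(+/-) alone. Regions held by a single list were most frequent in 5xFAD, at 7680, against 4384 in Tet1(+/-), 4122 in WT and 2691 in FAD/Tet1(+/-). With the full lists this order turned, with 52417 in Tet1(+/-), 3955 in 5xFAD, 2738 in WT and 1586 in FAD/Tet1(+/-). In the full lists, 6929 regions were missing from 5xFAD alone, 1800 from WT alone, 95 from Tet1(+/-) alone and 399 from FAD/Tet1(+/-) alone. The equal lists reached down to a −log10 p of 3.76 in 5xFAD, 7.69 in WT, 14.3 in Tet1(+/-) and 6.41 in FAD/Tet1(+/-). Weak 5xFAD peaks were thus set against only stronger peaks of the others, which can raise the number held by 5xFAD alone.

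**Figure D4:**
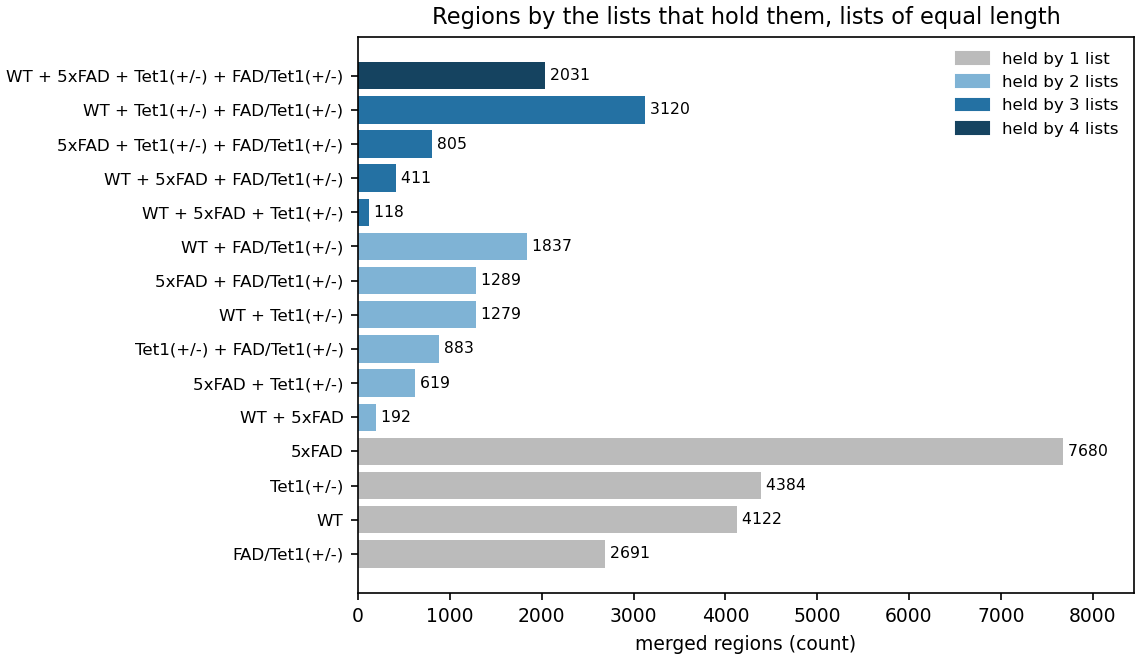
Bars give the number of merged regions held by each combination of the 4 lists of equal length, shaded by the number of lists. Regions held by WT, Tet1(+/-) and FAD/Tet1(+/-) but not 5xFAD (3120) outnumber every other combination of 3 lists.

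With all peaks, the X chromosome, present in a single copy in males, held fewer called regions per Mb than the autosomes in every genotype, and fewest in 5xFAD. The X to autosome ratio of peak density was 0.560 (0.522 to 0.601) in WT, 0.471 (0.452 to 0.490) in Tet1(+/-), 0.418 (0.382 to 0.457) in FAD/Tet1(+/-) and 0.132 (0.109 to 0.158) in 5xFAD. The 5xFAD list held 117 peaks on X and the WT list 816. With lists of equal length the ratios were 0.723 in WT, 0.748 in Tet1(+/-), 0.503 in FAD/Tet1(+/-) and 0.132 in 5xFAD. Among peaks with a fold enrichment of at least 5, the ratio was 0.539 in 5xFAD, 0.935 in WT, 0.656 in Tet1(+/-) and 0.831 in FAD/Tet1(+/-). The WT interval, 0.852 to 1.02, then included equal density. The 5xFAD interval, 0.427 to 0.673, then overlapped that of Tet1(+/-), 0.618 to 0.695. The X peaks that 5xFAD held were mostly shared, since 90.6% (83.8 to 95.2) of them overlapped WT, against 28.7% of its autosomal peaks. In FAD/Tet1(+/-) these shares were 87.1% and 59.5%. Of the deposited peaks, 71.2% in WT, 49.4% in 5xFAD, 67.1% in Tet1(+/-) and 58.1% in FAD/Tet1(+/-) had the list-wide background. That background takes no account of the single X copy, so copy number and 5hmC per copy were not separated. On the autosomes, 5xFAD peaks were densest on chromosome 19, at 1.37 times the autosomal mean, where the WT list had 0.883 times its own mean.

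**Figure D5:**
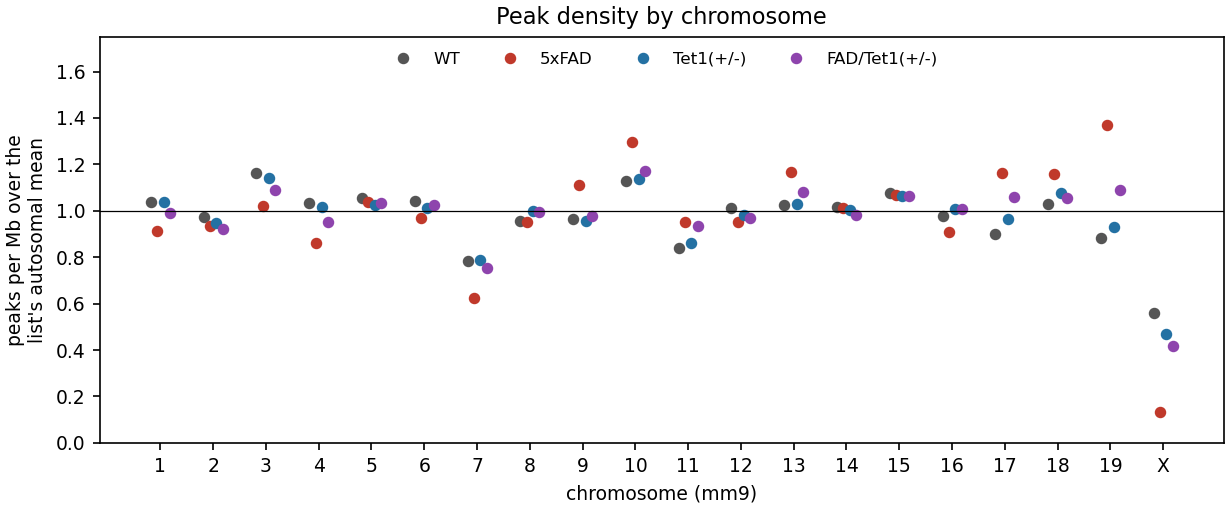
Points give peaks per Mb on each chromosome divided by the autosomal mean of the same list, for the 4 genotypes. On X the ratio is 0.560 in WT, 0.471 in Tet1(+/-), 0.418 in FAD/Tet1(+/-) and 0.132 in 5xFAD.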

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

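All tests in this part were chosen after the results were seen. The X to autosome ratio of peak density changed in opposite directions with the loss of a Tet1 copy, which was not tested. It differed by -0.0895 between Tet1(+/-) and WT, and by 0.286 between FAD/Tet1(+/-) and 5xFAD. In lists of equal length the first was within counting error, with 0.748 (0.690 to 0.810) in Tet1(+/-) and 0.723 (0.666 to 0.784) in WT, beside 0.503 in FAD/Tet1(+/-) and 0.132 in 5xFAD. The mitochondrial chromosome, left out of the comparisons, held called peaks in every list. Their highest fold enrichment was 1.84 in WT, 2.53 in 5xFAD, 5.25 in Tet1(+/-) and 2.67 in FAD/Tet1(+/-). The capture fragments at the summits of these peaks numbered 459, 399, 448 and 441 in the same order, at depths of 2.49, 1.54, 1.01 and 2.47 fragments per input fragment, so the folds do not follow the fragment counts. Captures were scaled to the input depth, so similar counts give a higher fold at a lower depth. The backgrounds at these summits also differed, at 100, 102, 83.6 and 66.1. Why the counts stayed alike at unlike depths was not tested, so the folds are not read as a difference between genotypes.

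The length of the Tet1(+/-) list stood apart, in the genotype with a reduced dose of a 5hmC-producing enzyme. Greater sequencing depth is argued against, since the recovered depth of 1.01 fragments per input fragment was the lowest of the 4 lists (next 1.54). Chance peaks near the threshold at low depth are argued against as the whole cause, since Tet1(+/-) also held 3.23 times as many peaks as WT with a fold enrichment of at least 10. More efficient capture in that batch of libraries cannot be told apart from the genotype, since there was 1 list per genotype. The 3 strongest WT peaks also had higher folds in Tet1(+/-), at 60.3, 36.0 and 38.1 against 34.7, 32.5 and 29.9 in WT, which either could give. The genotype itself stays open and untested.

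Strong WT peaks absent from the 5xFAD list formed another pattern, with 39.3% of the strongest 10% of WT peaks found in 5xFAD and 94.1% in FAD/Tet1(+/-). Lower sensitivity of the 5xFAD list stays open, since that share is the pattern itself and signal outside called peaks was not used here. The 3 strongest WT peaks had folds of 34.7, 32.5 and 29.9 in WT and 23.2, 15.8 and 14.0 in 5xFAD, while the 3 strongest 5xFAD peaks had 27.5, 34.7 and 24.4 in WT and 23.7, 23.2 and 21.3 in 5xFAD. A 5xFAD list made mostly of peaks placed at random is argued against, since 65.2% (64.4 to 66.0) of all its peaks overlapped the full Tet1(+/-) list. Random shifts gave 2.56% (27.7% against 0.510% in equal lists, where the Tet1(+/-) list is shortened). False peaks that the shared input gives both lists would overlap too, so a list made mostly of those is left open. A batch of the 5xFAD libraries cannot be told apart from the genotype, since there was 1 list per genotype, and the genotype stays open and untested.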

How the results depend on the processing

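No paired analysis was possible because each genotype is a single list and the replicate numbers of the libraries do not enter it. Leaving out replicates could not be run for the same reason, and the alternatives on genomic features and gene lists were not run, since no annotation of mm9 was used. Single counts and shares have no sign to reverse, but some orders between them turned. FAD/Tet1(+/-) overlapped Tet1(+/-) more than WT in full lists (85.9 and 60.2%) and less in equal lists (52.8 and 56.8%). The share found in WT was higher for 5xFAD than for Tet1(+/-) in full lists (29.2 and 23.8%) and lower in equal lists (21.0 and 49.5%). The X to autosome ratio of Tet1(+/-) lay below that of WT in full lists (0.471 and 0.560) but in equal lists the intervals overlapped (0.690 to 0.810 and 0.666 to 0.784). It lay above that of FAD/Tet1(+/-) with all peaks and below it at both stricter thresholds. The Tet1(+/-) list stayed the longest and the 5xFAD list the shortest in 5 of 5 alternatives, by peaks and by covered length. The share of 5xFAD peaks found in WT stayed the lowest of the 5 equal-list shares in 9 of 9. The pair of 5xFAD with Tet1(+/-), at 27.7% of 5xFAD peaks in equal lists, was not among those 5. 5xFAD kept the lowest X to autosome ratio in 4 of 4, although at a fold of at least 5 its interval overlapped that of Tet1(+/-). WT peaks absent from 5xFAD were found in FAD/Tet1(+/-) more often than 5xFAD peaks absent from WT in 7 of 7 alternatives with full lists and 9 of 9 with equal lists. Of 173 values, 118 moved beyond the interval of the reported value (for counts and lengths, by over 1.5 times) and 55 did not. Of 40 shares in the opposite direction, 30 moved. Stricter thresholds shorten the lists by construction, and the cause of the other shifts was not tested. The single list per genotype, the single input, labelled WT3, and the dependence on thresholds limit these results, and they were not ranked.

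Below, counts, lengths and X to autosome ratios are in the order WT, 5xFAD, Tet1(+/-) and FAD/Tet1(+/-). Overlap percentages are in the order 5xFAD in WT, Tet1(+/-) in WT, then FAD/Tet1(+/-) in 5xFAD, in Tet1(+/-) and in WT. Class percentages give the WT peaks absent from 5xFAD and then the 5xFAD peaks absent from WT that FAD/Tet1(+/-) held.

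With a −log10 q of at least 5, the lists held 12554, 4155, 43934 and 9233 peaks over 5.42, 1.69, 21.6 and 3.53 Mb. The X to autosome ratios were 0.761, 0.339, 0.533 and 0.633. Overlaps were 42.9, 24.0, 25.1, 89.5 and 66.2% in full lists and 26.5, 49.2, 38.9, 58.0 and 65.5% in equal lists. Class percentages were 41.5 and 29.7% in full and 54.8 and 19.0% in equal lists.

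With a fold enrichment of at least 5, the lists held 8264, 2303, 27931 and 5982 peaks over 3.70, 0.934, 15.0 and 2.35 Mb. The X to autosome ratios were 0.935, 0.539, 0.656 and 0.831. Overlaps were 49.2, 24.8, 24.0, 89.8 and 70.4% in full lists and 33.2, 46.7, 42.7, 56.7 and 71.8% in equal lists. Class percentages were 43.8 and 31.2% in full and 59.6 and 16.45% in equal lists.

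With peaks at the list-wide background only, chosen after seeing the data, the lists held 15915, 6552, 53241 and 10483 peaks over 6.50, 2.38, 23.7 and 3.69 Mb. The X to autosome ratios were 0.707, 0.231, 0.648 and 0.650. Overlaps were 24.8, 25.2, 21.3, 85.7 and 67.3% in full lists and 18.9, 52.7, 26.7, 54.35 and 61.7% in equal lists. Class percentages were 39.1 and 16.9% in full and 54.6 and 11.8% in equal lists.

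Requiring 50% of the peak to be covered gave overlaps of 26.9, 18.8, 28.8, 83.8 and 58.6% in full lists and 19.75, 39.3, 31.9, 52.6 and 55.9% in equal lists. Class percentages were then 36.8 and 21.8% in full and 44.4 and 18.3% in equal lists.

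Allowing a distance of up to 1 kb gave overlaps of 32.0, 31.3, 34.6, 88.4 and 63.3% in full lists and 22.7, 52.8, 37.3, 55.5 and 59.0% in equal lists. Class percentages were then 44.4 and 27.3% in full and 50.9 and 22.8% in equal lists.

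Holding each list to the length of the shortest gave overlaps of 21.0, 49.5, 34.4, 52.8 and 56.8%. Ranking equal lists by fold enrichment gave overlaps of 18.7, 50.8, 32.1, 52.8 and 56.7% and class percentages of 48.6 and 19.2%. Equal lists of 6628 peaks gave 24.2, 50.2, 35.8, 56.0 and 62.9% and 53.4 and 18.1%.

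Of the values in the orders given above, merging peaks within 500 bp moved 3, Tet1(+/-) in WT to 24.9% in full and 50.5% in equal lists, and FAD/Tet1(+/-) in Tet1(+/-) to 54.4% in equal lists. Using autosomes only moved 2, FAD/Tet1(+/-) in WT to 59.5% in full and 55.9% in equal lists.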

Other observations

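The tests in this part were chosen after the results were seen. In lists of equal length, 5xFAD regions were more unevenly spread over windows of 1 Mb than those of the other genotypes. In equal lists over 2425 autosomal windows of 1 Mb, the variance of the peak count over its mean was 5.91 in 5xFAD, 2.25 in FAD/Tet1(+/-), 2.20 in WT and 1.64 in Tet1(+/-). Windows with no peak numbered 348 in 5xFAD and 93, 90 and 49 in the other 3. At a shorter range, peaks with a neighbour within 10 kb made up 35.1% in 5xFAD, 33.4% in WT, 29.5% in FAD/Tet1(+/-) and 26.2% in Tet1(+/-). The equal 5xFAD list also kept weaker peaks, down to a −log10 p of 3.76, against at least 6.41 in the others. The window on chromosome 2 from 59000001 to 60000000 held 47 peaks in 5xFAD, 5 in WT, 8 in Tet1(+/-) and 15 in FAD/Tet1(+/-). The window on chromosome 8 from 63000001 to 64000000 held 33, 6, 7 and 17 in the same order. Among autosomal windows, the greatest excess of WT over 5xFAD was on chromosome 11 from 40000001 to 41000000, with 4 peaks in 5xFAD, 21 in WT, 15 in Tet1(+/-) and 13 in FAD/Tet1(+/-). Across all 2592 windows, which are not independent replicates, Spearman's rho of equal lists was 0.184 between WT and 5xFAD, 0.607 between 5xFAD and FAD/Tet1(+/-) and 0.633 between WT and FAD/Tet1(+/-). In full lists the values were 0.277, 0.683 and 0.646, so the order of the last pair turned. The 3 named windows were picked for their difference between 5xFAD and WT.

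A chromosome 9 place called only in 5xFAD carriers spanned 8242 bp, from 43849888 to 43858129. It held 3 peaks in 5xFAD, 3 in FAD/Tet1(+/-) and none in WT or Tet1(+/-), and included the peak with the smallest p in the 5xFAD list (−log10 p of 145). With carrier peaks within 10 kb of one another joined, of 479 regions called in both carrier lists and in neither other list, 1 had a −log10 p of at least 50, and the next reached 18.4. The 5xFAD transgenes are driven by the mouse Thy1 promoter, and whether the place is Thy1 was not examined here. The median recovered input level over the peaks of the place was 15.5 fragments (10 to 36) against a list-wide background of 3.04. These levels come from 3 positions of 1 input library, each read from both carrier lists.

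Whether the input library had the ordinary copy number at the place is left open by the level of 15.5. The test first used the lowest level with a Poisson chance under 0.001 as its bound, and at 0.00122 it did not pass. The median was taken only after the levels were seen and gave 1.5e-07. Input levels vary more than Poisson, so neither chance decides. Among 5xFAD peaks, 1.54% had an input at least as high as the first peak of the place, 0.362% as the second and 0.234% as the third. In FAD/Tet1(+/-) the shares were 2.29%, 0.344% and 0.127%.

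Extra copies of the place in 5xFAD carriers, with 1 such region found, may underlie the capture signal, but more 5hmC per copy cannot be told apart from them without an input from carriers. The place was also chosen for being called in carriers alone, so its count decides nothing. The raised level in the input labelled WT3 is left open. Neither sequence that maps there from elsewhere in the genome nor carrier DNA in that library was tested.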
